A study of Sus scrofa with 8 samples.

How the data were processed

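The samples were adipose tissue of 4 male pigs aged 180 days, 2 of the Landrace breed, described in the labels as leaner, and 2 of the Jinhua breed, described as fatty. Each animal gave an input library and an m6A immunoprecipitation (IP) library, 8 libraries in all. N6-methyladenosine (m6A) is a methyl mark on adenosines within RNA, and m6A-seq reads the RNA fragments that an antibody against the mark pulls down beside the RNA before the pull-down. Per the labels' protocols, total RNA was taken up in TRIzol, mRNA was purified with a bead kit, mRNA for the IP was broken by sonication and pulled down with an m6A antibody, and the libraries came from a stranded mRNA kit. The labels count 2 males per breed, so the replicates were separate animals.

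Per the submitters' processing notes, the tools and builds named were TopHat2 version 2.0.14, Sscrofa10.2 and susScr3, with no role or order. The quantifier, the annotation release, the use of strand in the quantification, the peak caller, its threshold and its filters were not given in the sources used here.

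The deposited expression table held 1 value per gene and input library for 22676 Ensembl pig gene IDs. Its values were taken as FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library) made by the authors. The table did not name the unit, so this reading rests on the gene column's name per the file headers, which is the one Cufflinks writes, and on values that were neither whole nor logged and whose sums differed between libraries. The deposited FPKM summed to 2802140 in Landrace replicate 1, 4143539 in Landrace replicate 2, 1540218 in Jinhua replicate 1 and 1920898 in Jinhua replicate 2. A single gene ID without a symbol took 63.2%, 73.8%, 40.1% and 51.0% of these sums, and the sums are not depths. Read numbers were not given, and a search of 430 genes with low values in all 4 libraries found no step that 1 read would leave (18 genes in the fullest of 160 bins of a value ratio), so the depth of the libraries is unknown and no interval for counting error could be set on an expression value. Genes listed at 0 numbered 7101, 6297, 6069 and 7005 in the same order of libraries. A listed 0 can be a failed estimate and is given here only as listed.

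The deposited peak lists, 1 per IP library and not pooled over animals, gave for each gene a transcript, the start and end of each peak on that transcript counted from 1, and the part of the transcript (5' UTR, coding sequence, 3' UTR, or UTR without an end named). They held no fold, score, p-value or read number, so peaks could be compared by position and presence alone. No chromosome coordinates are given below, because no pig genome was used here, and a search for the m6A sequence motif was not run for the same reason. The IP over input ratio by gene was not computed, because no expression values of the IP libraries were used. A further 4 expression columns and 4 peak lists carry names that match none of the samples described here and were not analysed here.

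Gene symbols came from the authors' peak lists for 7626 IDs and from an Ensembl name table for 5367, and 9683 IDs had none. Of 6083 IDs named in both sources, 335 had different symbols, and the authors' symbol was then used. Symbols that a spreadsheet had turned into dates were taken from the name table. FTO, ALKBH5, YTHDF1, YTHDF3, ADIPOQ, FABP4 and LPL matched no gene ID under these names and were not analysed here.

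Input expression was compared between the breeds with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided) on log2(FPKM + 1) for the 13693 gene IDs with a mean FPKM of at least 1 over the 4 input libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Deviations of animals with the same replicate number did not go together (correlation across genes -0.384). Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. All signed differences are Jinhua minus Landrace. Replicate numbers therefore did not pair the animals, and no replicate block was used. The fixed gene lists (26, for adipocyte functions, other cell types that adipose tissue or its surroundings could hold, and the m6A machinery) were tested with camera, preset correlation 0.01, and again with an estimated correlation. With the preset correlation the p rests on the spread across genes and not between animals. With an estimated correlation it rests on the 4 libraries alone, which are too few for a list to pass in practice. The step was tested on simulated values for the 13693 genes with the spread of the real ones: of 50 genes changed by each size, limma called 9 at a log2 change of 2, 40 at 4, 45 at 6 and 47 at 8, with 8 calls among unchanged genes. In the same simulation camera called the shifted list and 1 other list. For 2 animals against 2, an exact permutation test of a single value allows no two-sided p under 0.333.

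Peaks of different libraries on the same transcript were joined into 1 region where they overlapped by at least 1 bp. The presence of a peak was counted per region and per gene, and for every count restricted to the pair of animals of a breed the same count was made for the 2 crossed pairings (Landrace 1 with Jinhua 1, and Landrace 1 with Jinhua 2). The joining step gave the exact counts of all 15 presence patterns in 1863 simulated regions. Shares of peaks carry 95% Wilson intervals, which cover counting error only and not the spread between animals. Expression of genes with and without peaks was compared with a two-sided permutation test (100000 resamples) of the difference of medians, and calls against peaks with Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

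The tests, the gene lists, the named genes and most alternatives were fixed before the data were examined. Genes were named by rule: with fewer than 5 symbol-bearing genes past the threshold in a direction, the 10 with the smallest unadjusted p among genes whose groups did not overlap and whose mean FPKM was at least 5, and a set of m6A and adipocyte genes whatever their values. Further members of the gene lists were named after the values were seen. They come from the 4 members with the smallest unadjusted p in the direction of the list, for the 5 lists with the smallest camera p, and from adipocyte genes with an unadjusted p under 0.05 in either direction, and not all such members are named. ACTA1, MYLPF and the keratins were singled out for their levels. The rule for named peaks needed a fold or score, so the peaks named are those of genes with the highest mean input FPKM, also chosen after the data were seen. The alternatives were other pseudocounts, filters and scalings, limma without a trend, replicate blocks, leaving out each animal, other overlap rules and other definitions of a gene with peaks.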

Results

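The data covered the transcriptome and the m6A peaks of adipose tissue from 2 Landrace and 2 Jinhua pigs, with 1 input and 1 IP library per animal. The input libraries held 12761 (Landrace replicate 1), 13369 (Landrace replicate 2), 13462 (Jinhua replicate 1) and 12742 (Jinhua replicate 2) gene IDs with an FPKM of at least 1. Over the 13693 tested genes, log2(FPKM + 1) values correlated across genes, which are not independent replicates, with r = 0.819 between the Landrace animals and 0.839 between the Jinhua animals. The lowest correlation was 0.731, between Landrace replicate 1 and Jinhua replicate 1, and the highest was 0.878, between Landrace replicate 2 and Jinhua replicate 1. The values thus lay no closer within a breed than between breeds.

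The first comparison asked which transcripts differed in level between the fatty and the lean breed. No gene with a symbol passed the threshold. With limma, 2 gene IDs were higher and 3 were lower in Jinhua at an adjusted p of 0.0362, and all 5 had no symbol and were listed at 0 in both animals of a breed. ENSSSCG00000029667 was listed at 57.7 and 68.6 FPKM in the Jinhua animals and ENSSSCG00000028290 at 80.0 and 109.9, both at 0 in Landrace. ENSSSCG00000028380 was listed at 239.2 and 355.4 FPKM in the Landrace animals and ENSSSCG00000026058 at 103.2 and 87.2, both at 0 in Jinhua. At an unadjusted p under 0.05, 801 genes were higher and 530 lower. The groups did not overlap in 48.3% of the tested genes, where chance gives 33.3% for 2 animals against 2. Of these genes, 4132 were higher in Jinhua and 2481 lower. The crossed pairings of the animals set 22.9% and 27.3% of the tested genes apart. Genes of the same 4 animals are not independent, so 1 pairing can exceed 33.3% without a breed effect. The median difference of all tested genes was 0.15 (log2), and median-ratio scaling brought it to -0.01. limma made 0 calls with that scaling (1209 genes at an unadjusted p under 0.05), without any 1 of the 4 animals (316 to 2704 genes), and without genes listed at 0 in 2 or more libraries (1368 genes).

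Among genes with symbols, those with the smallest unadjusted p did not pass the threshold (adjusted p = 0.496 in limma for all 10 higher genes). CEP63, which encodes a centrosomal protein, had 3.91 ± 1.18 FPKM in Landrace and 17.2 ± 2.15 in Jinhua (mean ± SD, n = 2), a log2 difference of 1.91. NEK4, a protein kinase gene, had 7.07 ± 1.98 and 24.2 ± 2.05 FPKM. SPARCL1, which encodes a secreted glycoprotein of the extracellular matrix, had 55.3 ± 3.39 FPKM in Landrace and 170.5 ± 4.81 in Jinhua. GOLGA5, a golgin gene, had 7.59 ± 1.90 and 23.5 ± 0.769 FPKM, and TRIM37, a ubiquitin ligase gene, had 6.08 ± 0.342 and 16.3 ± 0.582 FPKM. CHL1, a cell adhesion gene, had 6.61 ± 0.215 FPKM in Landrace and 18.7 ± 2.96 in Jinhua. The other higher genes were ZC3H8 (log2 difference 1.65), UACA (1.37), FRRS1L (2.23) and CU459197.3 (2.15).

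In the other direction, SNORD86, a small nucleolar RNA, was listed at 79.2 and 139.1 FPKM in the Landrace animals and at 0 in both Jinhua animals (limma, adjusted p = 0.0689). CHGA, which encodes chromogranin A of secretory granules, had 10.9 ± 0.749 FPKM in Landrace and 0.569 ± 0.364 in Jinhua (n = 2), a log2 difference of -2.94. The protegrin gene NPG1 had 12.3 ± 2.06 and 0.474 ± 0.142 FPKM. The zinc transporter gene SLC39A7 had 11.1 ± 0.350 FPKM in Landrace and 1.91 ± 0.595 in Jinhua, and the folate carrier gene SLC19A1 had 26.4 ± 3.37 and 6.82 ± 1.36 FPKM. REXO2, an exonuclease gene, had 48.2 ± 0.369 and 12.7 ± 2.67 FPKM. VASN had a log2 difference of -2.20 and C16orf54 of -2.39. FRAS1 was listed at 24.2 and 6.88 FPKM in Landrace and the microRNA ssc-let-7d at 6.79 and 26.6, both at 0 in Jinhua. The adjusted p of these genes, SNORD86 aside, lay between 0.299 (NPG1) and 0.496. SNORD86 and the let-7 precursor are short RNAs, for which FPKM divides by a small length.

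Genes of m6A methylation went both ways, most of the writers with higher means in Jinhua, and none passed the threshold. WTAP, a subunit of the methyltransferase complex, had 20.02 ± 0.740 FPKM in Landrace and 40.5 ± 11.9 in Jinhua (n = 2; limma, log2 difference 0.95, adjusted p = 0.496). METTL14 had 3.83 ± 0.861 and 7.03 ± 0.416 FPKM, a log2 difference of 0.75 (limma, adjusted p = 0.496). METTL3, the catalytic subunit, had 12.1 ± 3.92 FPKM in Landrace and 19.1 ± 1.05 in Jinhua, and the reader gene YTHDF2 had 13.7 ± 5.52 and 18.6 ± 2.39 FPKM. Their adjusted p were 0.516 and 0.612. The fixed list of m6A writers had a median log2 difference of 0.67, with 8 of 10 measured members above 0 and 7 of them with groups apart. Its adjusted p in camera was 0.0548, and 0.964 with an estimated correlation, as for every list. In camera the list was called with quantile normalization (adjusted p = 0.0488) and with no filter on low values (0.0454). It moved away from a call with a mean FPKM of at least 5 (0.0989), the replicate block (0.0748) and the crossed block (0.101). Its median was 0.59 without Landrace replicate 1 and 0.82 without Landrace replicate 2. Without Jinhua replicate 1 it was 0.63, and without Jinhua replicate 2 it was 0.72. The writers below 0 were RBM15 (log2 difference -0.09) and RBM15B (-0.28), whose signs were not followed under the alternatives. METTL16 and METTL5, other RNA methyltransferase genes on that list, had log2 differences of 0.88 and 0.98.

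**Figure D1:**
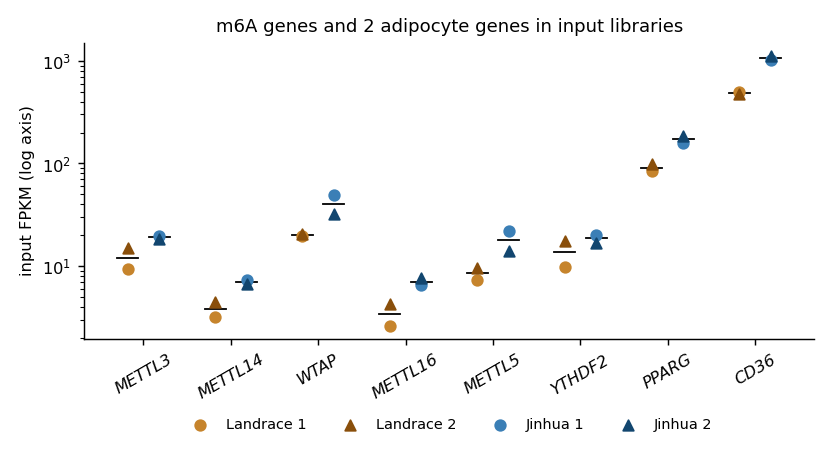
Input FPKM on a log axis of m6A genes and of the adipocyte genes PPARG and CD36 in each animal, with circles for replicate 1, triangles for replicate 2 and lines for the means of each breed. The Jinhua animals lay above both Landrace animals for METTL3, METTL14, WTAP, METTL16, METTL5, PPARG and CD36, and the YTHDF2 values of the breeds overlapped (17.6 in Landrace replicate 2 and 16.9 in Jinhua replicate 2).

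Genes of adipocyte function went both ways, and none passed the threshold. PPARG, the transcription factor of adipocyte differentiation, had 91.0 ± 10.24 FPKM in Landrace and 172.7 ± 19.0 in Jinhua (n = 2; limma, log2 difference 0.92, adjusted p = 0.496). CD36, a fatty acid transporter, had 486.2 ± 16.1 and 1068 ± 60.4 FPKM, and GPAM, the first enzyme of triglyceride synthesis, had 5.24 ± 1.72 and 14.1 ± 2.72 FPKM. In the other direction, CFD, which encodes the adipokine adipsin, had 701.9 ± 59.0 FPKM in Landrace and 220.9 ± 139.5 in Jinhua (log2 difference -1.82), and the beta-adrenergic receptor gene ADRB1 had 35.6 ± 20.1 and 5.81 ± 0.0679 FPKM (-2.31). FASN, fatty acid synthase, had 11240 and 4859 FPKM in the Landrace animals and 1637 and 4782 in the Jinhua animals, a log2 difference of -1.40 (limma, adjusted p = 0.525). The lipid droplet gene PLIN1 had 4137 ± 1668 and 2067 ± 428.8 FPKM, and the triglyceride lipase gene PNPLA2 had 1841 ± 1535 and 582.4 ± 124.5 FPKM, with 2926 in Landrace replicate 1 and 755.7 in Landrace replicate 2. CEBPA had 552.5 and 115.4 FPKM in the Landrace animals and 77.6 and 148.4 in the Jinhua animals, so that its higher Landrace mean rested on Landrace replicate 1. SCD, stearoyl-CoA desaturase, differed more within the breeds, with 1049 and 7065 FPKM in the Landrace animals and 1230 and 10690 in the Jinhua animals, and its log2 difference of 0.41 became -0.14 with quantile normalization. LEP (leptin) had 102.7 ± 22.8 and 99.8 ± 17.9 FPKM, and LIPE had a log2 difference of -0.29. The lists of adipocyte identity (median log2 difference -0.13, 14 measured), fatty acid and triglyceride synthesis (-0.01, 19 measured) and lipolysis (-0.14, 12 measured) were not called by camera (adjusted p between 0.231 and 0.951). Their medians depended on single animals. Without Landrace replicate 1, adipocyte identity had 0.07 and lipolysis 0.175. Lipolysis had -0.75 without Landrace replicate 2, and fatty acid and triglyceride synthesis had 0.775 without Jinhua replicate 1.

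Of the 26 fixed lists, camera called 3 with the preset correlation. With an estimated correlation the adjusted p was 0.964 for every list. That setting rests on the few libraries alone and could hardly have called a list, so it decides nothing about the 3. None of the members of the 3 called lists passed the threshold over all genes tested, nor when adjusted over the list alone. Genes of oxidative phosphorylation were higher in Jinhua (median log2 difference 0.48, and 0.30 with median-ratio scaling, camera adjusted p = 0.0137). This p, like that of the other called lists, rests on the spread across genes and not between animals. Of 27 measured members 23 lay above 0, and 17 had both Jinhua animals above both Landrace animals, none the reverse. Over all 13693 tested genes, 4132 lay apart with Jinhua higher and 2481 with Jinhua lower, counts to set beside each list. The ATP synthase gene ATP5O had 224.0 ± 62.8 FPKM in Landrace and 507.8 ± 5.17 in Jinhua (n = 2), NDUFB3 and NDUFA1 of complex I had 33.5 ± 16.9 and 81.1 ± 9.62, and 237.1 ± 84.9 and 550.1 ± 85.2, and SDHB of complex II had 132.0 ± 33.6 and 257.8 ± 3.74. Without Jinhua replicate 2 the list lost its call (adjusted p = 0.426, median 0.39). Interferon-stimulated genes were higher in Jinhua too (median log2 difference 0.62, and 0.44 with median-ratio scaling, camera adjusted p = 0.0142, again across genes). Of 17 measured members 15 lay above 0, 13 had the groups apart in that direction and 1 in the other. IFIT1 had 12.8 ± 3.79 FPKM in Landrace and 29.0 ± 4.65 in Jinhua, OAS1 had 70.0 ± 30.3 and 153.5 ± 14.04, and OAS2 had 24.3 ± 0.895 and 42.9 ± 4.53. This call ended without Jinhua replicate 1 (adjusted p = 0.0515, median 0.47) and without Jinhua replicate 2 (adjusted p = 0.0771, median 0.76).

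The skeletal muscle list was lower in Jinhua (median log2 difference -1.70, adjusted p = 8.96e-04), and all 19 measured members lay below 0. This rested on 1 library. All 19 genes had their highest FPKM in Landrace replicate 2, between 4.95 and 36.8 times the next library. ACTA1, skeletal muscle actin, had 1511 FPKM there against 50.6 in Landrace replicate 1, 38.6 in Jinhua replicate 1 and 72.2 in Jinhua replicate 2. MYLPF, a fast myosin light chain, had 510.7 FPKM there against 5.83, 10.7 and 16.5. ATP2A1, the calcium pump of fast fibres, had 42.5 FPKM there, and the troponin gene TNNI1 had 59.3. Without Landrace replicate 2 the list turned to the other direction and was not called (adjusted p = 0.502).

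**Figure D2:**
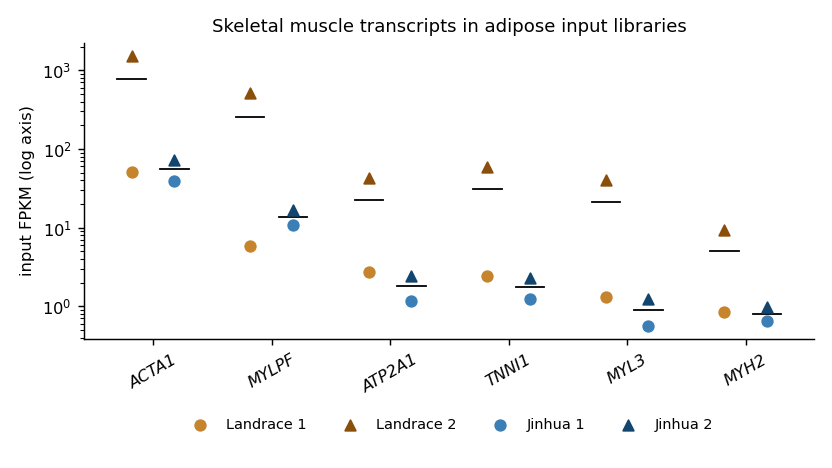
Input FPKM on a log axis of 6 skeletal muscle genes in each animal, with circles for replicate 1, triangles for replicate 2 and lines for the means of each breed. Landrace replicate 2 lay above the other 3 libraries for every gene drawn, with 1511 FPKM of ACTA1 and 9.37 FPKM of MYH2.

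The extracellular matrix list was lower in Jinhua without passing the threshold (median log2 difference -0.34, 13 of 20 below 0, camera adjusted p = 0.0518). With an estimated correlation its adjusted p was 0.964 in camera, as for every list. It was called without Landrace replicate 1 (adjusted p = 2.32e-05), with quantile normalization (0.0384) and with no filter on low values (0.0454), and without Landrace replicate 2 its median turned to 0.21 (adjusted p = 0.752). Its members COL6A2 (353.5 ± 68.4 FPKM in Landrace and 99.9 ± 12.03 in Jinhua, n = 2), COL5A1 (log2 difference -1.99) and COL4A2 (-1.63) had groups apart. The other 21 lists had adjusted p of 0.146 or more, but leaving out an animal brought camera calls for some: adipose progenitors (0.0299) and macrophages (0.0408), both lower, without Landrace replicate 1, ribosomal proteins (0.0285), higher, without Landrace replicate 2, and blood (0.0340), immediate early and heat shock genes (0.0280) and smooth muscle and pericytes (0.0273), all lower, without Jinhua replicate 1. Their median log2 differences were 0.58 for ribosomal proteins, 0.36 for fatty acid oxidation, 0.47 for cholesterol synthesis, 0.46 for inflammation, 0.40 for thermogenic adipocytes, 0.22 for m6A erasers and readers, 0.15 for macrophages, 0.18 for nerve, 0.04 for the cell cycle, 0.03 for insulin signalling, 0.01 for the circadian clock and 1.09 for epithelium. Those of smooth muscle and pericytes (-0.39), adipose progenitors (-0.17), blood (-0.43), endothelium (-0.79), lymphocytes (-0.22) and immediate early and heat shock genes (-0.32) lay below 0. Single animals moved these medians too, among others as follows. Without Landrace replicate 1, cholesterol synthesis had -0.13, inflammation -0.07, macrophages -0.37 and immediate early and heat shock genes 0.225. Cholesterol synthesis had 0.95 without Landrace replicate 2. Epithelium had -1.01 without Jinhua replicate 1 and 3.53 without Jinhua replicate 2. Without Jinhua replicate 2, thermogenic adipocytes had -0.30 and blood 0.14. All list medians carry the shift of all tested genes. With median-ratio scaling those of macrophages (-0.03), the cell cycle (-0.10), insulin signalling (-0.13) and the circadian clock (-0.15) turned below 0, with quantile normalization the last 3 did, and with median-ratio scaling fatty acid oxidation had 0.17, m6A erasers and readers 0.06 and nerve 0.06. Without scaling, median and test differed in sign for the macrophage, cell cycle, nerve, insulin signalling and thermogenic lists (median above 0, test toward lower, and a mean of -0.03 for the thermogenic list) and for fatty acid and triglyceride synthesis (median below 0, mean 0.10, test toward higher).

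The second comparison described the m6A peaks. The authors' lists held 8909 peaks in 4798 genes for Landrace replicate 1, 19039 in 8152 genes for Landrace replicate 2, 20688 in 8776 genes for Jinhua replicate 1 and 16116 in 7354 genes for Jinhua replicate 2. Peaks had a median width of 161 bp in Landrace replicate 1 and of 156 or 157 bp in the others, and covered 1528.8, 3031.1, 3239.4 and 2670.9 kb of transcript in the same order. The 2 Landrace libraries thus differed more from each other than the breeds did. A gene with peaks had on average 1.86 peaks in Landrace replicate 1 and between 2.19 and 2.36 in the others.

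Most peaks lay in coding sequence. In Landrace replicate 1, 71.7% of peaks (95% Wilson interval 70.8 to 72.6) were in coding sequence, 20.5% (19.7 to 21.4) in the 3' UTR and 7.2% (6.7 to 7.8) in the 5' UTR. Coding shares in the other libraries were 73.6%, 72.8% and 73.0%, and 3' UTR shares were 19.1%, 21.2% and 21.7%. The 5' UTR share was 6.7% (6.4 to 7.1) in Landrace replicate 2, 5.4% (5.1 to 5.7) in Jinhua replicate 1 and 4.7% (4.4 to 5.1) in Jinhua replicate 2, so both Landrace libraries lay above both Jinhua libraries beyond counting error. With 2 animals per breed an exact permutation test cannot give a two-sided p under 0.333.

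**Figure D3:**
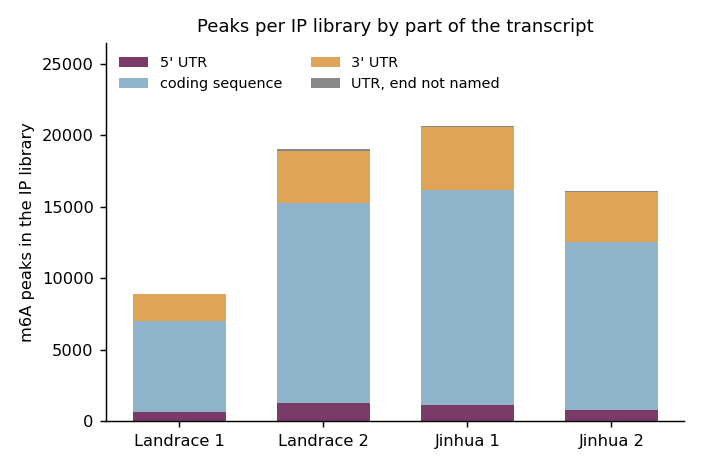
Number of m6A peaks in each IP library, stacked by the part of the transcript given in the authors' lists. Coding sequence held the largest part in each library (71.7% to 73.6%), and Landrace replicate 1 had the fewest peaks (8909).

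Peaks shared between animals were counted in both directions. Of the peaks of Landrace replicate 1, 80.7% (95% Wilson interval 79.9 to 81.5) overlapped a peak of Landrace replicate 2, 76.1% (75.2 to 77.0) a peak of Jinhua replicate 1 and 71.0% (70.0 to 71.9) a peak of Jinhua replicate 2. Of the peaks of Jinhua replicate 2, 75.2% (74.6 to 75.9) overlapped a peak of Jinhua replicate 1, against 65.2% for Landrace replicate 2 and 40.9% for Landrace replicate 1. These shares are bounded by the length of the lists, since the 8909 peaks of Landrace replicate 1 can cover only part of a longer list, and their order does not rank the animals by likeness. Peaks of Landrace replicate 2 overlapped those of Jinhua replicate 1 (74.3%) more often than those of Landrace replicate 1 (39.7%), and peaks of Jinhua replicate 1 overlapped those of Landrace replicate 2 (68.5%) more often than those of Jinhua replicate 2 (59.9%). Joined over the libraries, the peaks made 27320 regions, of which 5065 were present in all 4.

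The third comparison asked which peaks and genes carried m6A in a single breed. Regions present in both animals of a breed and in neither of the other numbered 633 for Landrace and 1898 for Jinhua. The crossed pairings gave 182 regions for Landrace 1 with Jinhua 1 and 423 for Landrace 2 with Jinhua 2, and 282 for Landrace 1 with Jinhua 2 and 3227 for Landrace 2 with Jinhua 1. By gene, 105 had peaks in the Landrace animals alone and 599 in the Jinhua animals alone, of 9977 genes with a peak in any library and 4160 with a peak in all 4. Of the 105 genes, 94 also had higher input expression on average in Landrace, and of the 599, 548 had it in Jinhua. The counts thus do not separate methylation from transcript abundance. The crossed pairings gave 34 and 82 genes, and 25 and 936. The breed pairing was therefore not the one with the most restricted genes in total (704 against 116 and 961). The total follows list length in part, since the largest crossed pair joins the 2 libraries with the most genes with peaks. The product of the 2 counts, which allows for list length, was largest for the breed pairing (62895 against 2788 and 23400). By region the breed product was also the largest, with a lead smaller in proportion (1201434 against 76986 and 910014). Among genes with a mean FPKM of at least 30, a crossed pairing had the larger product (2856 against 1026). The restricted counts depended on single libraries. Without Landrace replicate 1 the gene counts were 638 for Landrace and 684 for Jinhua, without Landrace replicate 2 they were 143 and 2584, without Jinhua replicate 1 they were 410 and 971, and without Jinhua replicate 2 they were 151 and 1271. The region counts without the same animals were 3761 and 2304, 1303 and 5904, 1532 and 4509, and 917 and 5504.

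**Figure D4:**
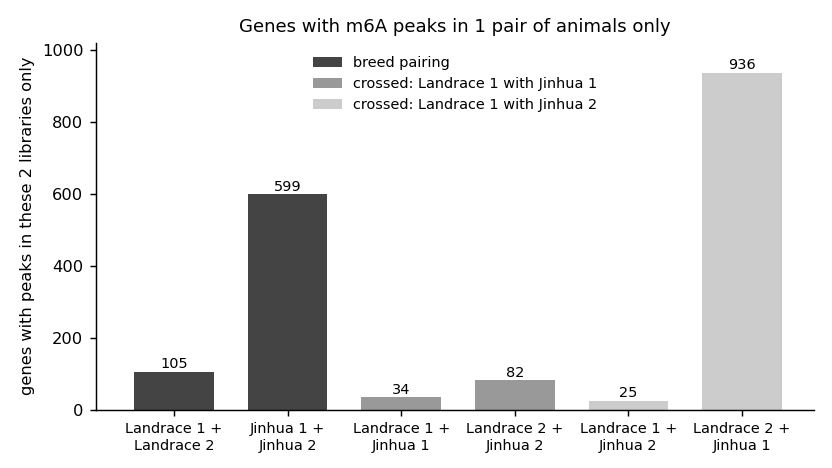
Number of genes with m6A peaks in both libraries of 1 pair of animals and in neither of the other pair, for the breed pairing (dark bars) and the 2 crossed pairings (lighter bars). The largest bar, 936 genes, is the crossed pair of Landrace replicate 2 with Jinhua replicate 1, the 2 libraries with the most genes with peaks. The breed pairs have 105 and 599 genes.

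The breed-restricted peaks named here are those in the transcripts of the highest mean input FPKM. In Landrace alone, peaks lay in the coding sequence of FASN (positions 3638 to 3820 of ENSSSCT00000029960), of the collagen genes COL3A1 (1551 to 1740 of ENSSSCT00000017459) and COL4A1 (1481 to 1652 of ENSSSCT00000010462), of YBX1, PSAP and the mitochondrial phosphate carrier gene SLC25A3, in the 3' UTR of UQCR10 (211 to 386 of ENSSSCT00000031506) and in the 5' UTR of CTSB. In Jinhua alone, peaks lay in the coding sequence of FASN (3450 to 3626 of the same transcript), GLUL (glutamine synthetase, 735 to 910 of ENSSSCT00000016935), PC (pyruvate carboxylase, 2061 to 2170 of ENSSSCT00000014129) and ATP5B, in the 3' UTR of LGALS1 (706 to 928 of ENSSSCT00000000131), CFL1 and C9orf16, and in an untranslated region of GPX3 (661 to 891 of ENSSSCT00000018610). The Landrace and Jinhua peaks of FASN lay side by side on the transcript without overlapping. The gap between them was shorter than the shortest listed peak (100 bp). Positions alone thus do not tell 2 separate sites from 1 stretch called with different edges. Peaks shared by all 4 libraries included FTL (ferritin light chain, positions 20 to 185 of ENSSSCT00000003500, 5' UTR), EEF1A1 (70 to 276 of ENSSSCT00000004960, coding), FASN (118 to 350, coding), SCD (453 to 771 of ENSSSCT00000011546, coding), COL3A1 (1860 to 2371, coding) and the ribosomal protein genes RPS27, RPS12 and RPS25.

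Among the m6A genes, METTL3 had 0 peaks in Landrace replicate 1, 2 in Landrace replicate 2, 3 in Jinhua replicate 1 and 1 in Jinhua replicate 2, and the region at positions 724 to 905 of ENSSSCT00000026886 in its coding sequence was shared by the last 3. METTL14 (1387 to 1549 of ENSSSCT00000009980) and WTAP (744 to 966 of ENSSSCT00000004478) each had a coding region in the same 3 libraries. YTHDF2 had a coding region in all 4 (1301 to 1510 of ENSSSCT00000027438). Of the adipocyte genes, LEP had 1 peak per library, in its 3' UTR (351 to 530 of ENSSSCT00000018060). SCD had 6, 10, 9 and 8 peaks, most of its regions in the 3' UTR. LIPE (362 to 685 of ENSSSCT00000003352) and PNPLA2 (919 to 1176 of ENSSSCT00000014036) each had a coding region in all 4 libraries. PPARG had 1, 3, 4 and 1 peaks. CEBPA had a coding region in the Jinhua animals alone (911 to 1040 of ENSSSCT00000003167), and PLIN1, with 5317 FPKM in Landrace replicate 1, had no peak in that library or in Jinhua replicate 2.

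The fourth comparison asked how expression and m6A peaks went together. Genes with a peak in all 4 libraries had a median log2(FPKM + 1) of 4.81 (quartiles 3.88 and 6.02, 4160 genes) against 0.15 (0.00 and 1.34) for the 12699 genes without a peak, a difference of 4.65 (permutation test across genes, two-sided p = 1e-05, the smallest that 100000 resamples can give). The difference was between 4.65 and 4.82 in each input library, and 2.46 among genes with a mean FPKM of at least 1. The share of genes with a peak in all 4 libraries rose from 0.6% at a mean FPKM of 1 to 3 to 44.3% at 10 to 30 and 63.2% at 100 to 300, and was 47.6% above 300.

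**Figure D5:**
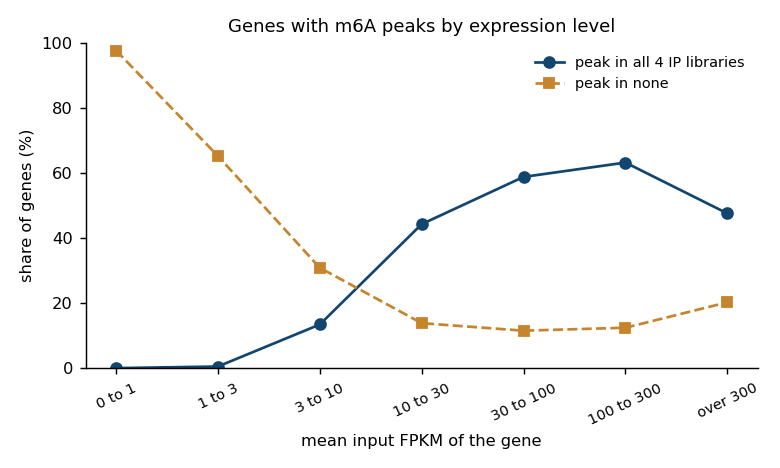
Share of genes with a peak in all 4 IP libraries (circles) and in none (squares) by the mean input FPKM of the gene. The first share is highest at 100 to 300 FPKM (63.2%), and the second falls from 97.6% above 0 and up to 1 FPKM to 11.6% at 30 to 100, with 20.3% above 300.

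Differential expression and m6A peaks were set against each other last. The 5 called gene IDs were listed at 0 in both animals of a breed, which all but rules out a peak in all 4 libraries, so their overlap with such genes decides nothing. None of the 5 had a peak in any library, where 30.4% of the other tested genes had peaks in all 4 (Fisher's exact test, two-sided, p = 1.0 for the 2 higher and 0.558 for the 3 lower). Against a peak in at least 1 library, which 72.2% of the others had, the Fisher's exact p values were 0.0775 and 0.0216. A value listed at 0 in both animals of a breed also lowers the chance of a peak in any library. These p values, on 2 and 3 genes, therefore decide nothing either. At an unadjusted p under 0.05, 184 of 801 higher genes (23.0% against 30.8% of the others, odds ratio 0.669) and 111 of 530 lower genes (20.9% against 30.7%, odds ratio 0.597) had peaks in all 4 libraries (Fisher's exact test, p = 1.91e-06 and 8.14e-07), a threshold chosen after the data were seen. A gene low in either breed is less likely to have peaks in all 4 libraries, so a lower share can follow from the difference in expression alone.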

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

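The crossed block, the filter on genes listed at 0, the FPKM minimum of 30, the unadjusted p and the location shares in genes with peaks in all 4 libraries were alternatives chosen after the data were seen. The 2 higher and 3 lower genes of the input comparison numbered 3 and 4 with a pseudocount of 0.1, 2 and 4 with a mean FPKM of at least 5, 2 and 3 with quantile normalization and with an added log2 fold change of at least 1. They numbered 0 and 0 with a pseudocount of 5, with no filter on low values, with median-ratio scaling, without a trend, without genes listed at 0 in 2 or more libraries, and without each animal in turn (0 to 0). Leaving out an animal leaves 1 sample in a breed, assumed to vary like the others. With the replicate block the counts were 0 and 0. Deviations of same-numbered animals correlated at -0.384, so the numbers do not pair the animals, and a crossed replicate block, which joins Landrace 1 with Jinhua 2, also gave 0 and 0. limma gave 695 genes with an unadjusted p under 0.05 with the block and 1603 with the crossed block, against 1331. The cause was not tested, except that the last filter removed all 5 calls by construction.

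The 3 called lists numbered 5 with no filter on low values and with quantile normalization, where extracellular matrix and m6A writers were added, and 1 to 7 without each animal. The block left 3. The skeletal muscle list reversed without Landrace replicate 2 (adjusted p = 0.502, range over all alternatives 3.76e-24 to 0.502), as did ACTA1 (0.06, and -4.81 without Landrace replicate 1) and MYLPF (1.07 and -5.16), since that library alone held high values. Of 1082 log2 differences of the 77 named genes under an alternative, 1018 kept their sign and side of the threshold, 50 lost their call, 2 gained one and 12 reversed. Only 5 of the 77 had a call to lose, and all 50 losses were theirs. The 1018 therefore count mostly genes that stayed without a call. Besides ACTA1 and MYLPF, the difference reversed for SCD with quantile normalization (-0.14), without Landrace replicate 1 (-0.96) and without Jinhua replicate 2 (-1.15), for LIPE (0.33) and KRT8 (-0.42) without Landrace replicate 1, for LEP without Landrace replicate 1 (0.19) or Jinhua replicate 1 (0.15), for KRT8 (-1.36) and KRT18 (-1.01) without Jinhua replicate 1 and for KRT19 (-0.04) without Jinhua replicate 2. Without each animal the largest values the other way were 1.97 for SCD, -0.92 for LIPE, -0.26 for LEP, 3.53 for KRT8, 3.96 for KRT18 and 1.11 for KRT19. The cause was not tested. SNORD86 passed the threshold with a pseudocount of 0.1 (limma, adjusted p = 0.0244) and a mean FPKM of at least 5 (0.0410), with adjusted p from 0.0244 to 0.536 over its alternatives.

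The share of peaks of the shorter list found in the other animal moved from 80.7% to 72.2% in Landrace and from 75.2% to 68.0% in Jinhua with a reciprocal overlap of 50%, and to 77.1% and 72.1% with centres within 100 bp, as stricter rules must. Breed-restricted regions stayed within 1.5 times under both rules. Without each animal they ranged from 917 to 3761 for Landrace and from 2304 to 5904 for Jinhua, and restricted genes from 143 to 638 and from 684 to 2584, because the rule then asks for presence or absence in fewer libraries. With a mean FPKM of at least 30 the restricted genes numbered 19 and 54, fewer genes being counted. No paired analysis was made for the peaks, because the replicate numbers do not pair the animals and the counts come from no test. In genes with peaks in all 4 libraries the coding share was 72.1% in Landrace replicate 2, 71.7% in Jinhua replicate 1 and 72.2% in Jinhua replicate 2, the 3' UTR share 21.0%, 22.7% and 23.1%, and the 5' UTR share 5.1% in Jinhua replicate 1 and 4.2% in Jinhua replicate 2. The Fisher's exact p of the lower genes was 0.0216 with a peak in at least 1 library. It rests on 3 genes listed at 0 in both animals of a breed and decides nothing. At an unadjusted p under 0.05 the Fisher's exact p was 1.91e-06 for higher and 8.14e-07 for lower genes, where more genes enter. Peaks per library stayed within 1.5 times with touching peaks merged. The log2 difference between genes with and without peaks kept its direction and its side of the threshold, but moved from 4.65 to 3.99 for a peak in at least 2 libraries and to 2.46 among genes with a mean FPKM of at least 1, where genes listed near 0 are left out.

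Alternatives that need a fold, score or p of each peak (stricter peaks, equal numbers of top peaks), counts, the genome (motif) or expression values of the IP libraries were not run. Depth is unknown, so a gene or peak missing from a library cannot be told from one below its detection limit.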

Other observations

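The tests of muscle tissue, of the products of restricted counts, of ribosomal protein and fatty acid oxidation genes, the comparison of gene lists with matched lists and the crossed regroupings of expression were chosen after values they rest on had been seen, and the test of products was divided into all genes and genes with a mean FPKM of at least 30 after its result was seen.

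Among genes with a symbol, those with the most peaks were DST, MACF1 and KMT2D. The counts were not scaled to transcript length, so they do not rank genes by density of peaks. DST, a cytoskeletal linker, had 20, 34, 36 and 27 peaks (Landrace replicates 1 and 2, Jinhua replicates 1 and 2), MACF1, another linker of actin and microtubules, had 12, 29, 29 and 29, and the histone methyltransferase gene KMT2D had 12, 20, 22 and 14. Abundant transcripts without a peak in any library included the ribosomal protein genes RPLP2 (mean 4004 FPKM), RPS21 (3608) and RPS3 (2474), GPX4 (1512) and TMSB10 (1376).

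Set against 10000 lists matched on mean expression but not on transcript length, oxidative phosphorylation had 21 of 27 genes with a peak in all 4 libraries, where matched lists had a median of 15 and a central 95% of 10 to 20 (permutation p = 0.0298, adjusted p = 0.258 over 26 lists). Insulin signalling had 12 of 17 (4 to 11 in matched lists, adjusted p = 0.242). Skeletal muscle had 0 of 19 (4 to 12 in matched lists, adjusted p = 0.0052), but its mean expression came from Landrace replicate 2, so the matching decides nothing for it. The m6A writers had 3 of 10, at a matched median of 3. It was asked whether ribosomal protein genes have such peaks less often than genes of like expression: 11 of 27 had them, at a matched median of 14 and within a central 95% of 9 to 19. It was also asked whether fatty acid oxidation genes have them more often: 14 of 17 had them, at a matched median of 10 and at the upper edge of 6 to 14. Both counts lay on the side asked about without leaving the range, so both questions stay open.

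Skeletal muscle transcripts stood out in Landrace replicate 2, an adipose sample by its label, with 1511 FPKM of ACTA1, while 14 of the 19 measured list genes had at least 1 FPKM in all 3 other libraries and 1 gene is also on another list. Scaling of that library is argued against, since its median log2 ratio to the others was 3.92 higher for the muscle list than for all tested genes. A breed difference is argued against as well: Landrace replicate 1 lay below the mean of the Jinhua animals in 15 of the 19 genes. A candidate explanation is muscle tissue in the sample of that animal, in which case its IP list should hold peaks in muscle genes, and it did in 18 of 19, against 0 in Landrace replicate 1, 2 in Jinhua replicate 1 and 4 in Jinhua replicate 2. Any muscle RNA present before the IP would give such peaks, so muscle tissue is not told from another source of that RNA.

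More genes had peaks in Jinhua alone (599) than in Landrace alone (105), a ratio of 5.70. The ratio was 1.07 without Landrace replicate 1, 18.1 without Landrace replicate 2, 2.37 without Jinhua replicate 1 and 8.42 without Jinhua replicate 2, so the few peaks called in Landrace replicate 1 may account for it in part, although each removal also asks for a peak in 1 library only of that breed. If peak calls follow transcript abundance, genes restricted to a crossed pair should be higher in that pair, relative to genes with peaks in all 4 libraries. This was so in 3 of the 4 crossed sets (relative median log2 differences 0.65, 0.26 and 0.33). It was not so in Landrace 1 with Jinhua 2 (-0.16, 25 genes, permutation p = 0.150). The difference was 1.09 for genes restricted to Landrace and 0.52 for those restricted to Jinhua. Of these breed-restricted genes, 89.5% and 91.5% were higher in their own breed, against 40.0% to 82.4% in the crossed sets. Abundance thus went with most of the breed-restricted calls, and whether it accounts for them stays open. A breed effect should make the product of the 2 restricted counts larger for the breed pairing than for the crossed ones. Over all genes it was 2.69 times the largest crossed product (95% interval 1.72 to 4.21). By region it was 1201434 against 910014, a lead smaller in proportion. For genes with a mean FPKM of at least 10 it was 13248 against 8808. At a mean FPKM of at least 30 it was 0.359 times the largest crossed product (0.174 to 0.740). The intervals count genes and not animals. Since 3 pairings allow no share under 0.333, a breed effect stays open.

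The 5' UTR share of peaks was higher in both Landrace libraries. If different genes carried the peaks, the shares should overlap among genes with a peak in all 4 libraries. The lower Landrace share there still exceeded the higher Jinhua share by 1.3 percentage points (6.4%, interval 6.0 to 6.9, against 5.1%, interval 4.7 to 5.5). This argues against a difference in the set of genes with peaks as the sole explanation. The number of peaks per gene was not held fixed, so the same genes can still weigh differently in each library. They gave 8132 and 12044 peaks in the Landrace libraries, and 12489 and 10899 in the Jinhua libraries. Differences between the breeds and between the libraries, such as fragment size or IP efficiency, were not tested and stay open.

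Setting Landrace 1 and Jinhua 2 against Landrace 2 and Jinhua 1, limma called 167 genes, against 5 for the breeds and 0 for the remaining pairing (1331, 609 and 224 genes at an unadjusted p under 0.05 for the breeds, the first and the remaining crossed pairing), which points to a structure of the samples beside breed. Of these 167 genes, 70 were listed at 0 in both animals of 1 pair, and limma called 107 without genes listed at 0 in 2 or more libraries, while this pairing set 27.3% of the tested genes apart, against 48.3% for the breeds and 33.3% by chance. The pairing also splits the libraries by genes listed at 0: 7101 and 7005 in Landrace 1 and Jinhua 2, against 6297 and 6069. Of the tested genes, 151 were at 0 in Landrace 1 and Jinhua 2 alone, and 6 in the other pair alone. Whether this split explains the calls was not tested.

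Keratin genes of simple epithelia differed between single animals. KRT8 was at 52.2 FPKM in Jinhua replicate 1 and 12.1 in Landrace replicate 2, against 0.615 in Landrace replicate 1 and 0.791 in Jinhua replicate 2, KRT18 was at 43.7, 6.34, 0.126 and 0.427 FPKM in the same order, and KRT19, the other measured gene of that list, was highest in Jinhua replicate 2 (3.42, 4.34, 2.87 and 8.83 FPKM).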
